A study of Caenorhabditis elegans with 2 samples.

How the data were processed

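The samples were 2 biological replicates of L2 larvae of *C. elegans* strain OP62, per the labels a line that stably expresses LIN-11 with a C-terminal GFP-FLAG tag. Whole animals of pooled sexes were used. Per the labels, the antibody entry names LIN-11 and the description names a GFP fusion, and the reagent is not otherwise given in the sources used here. The replicates are labelled as biological replicates and came from different stock sources, and the label of replicate 2 gives a fragment size range of 150 to 350 bp while that of replicate 1 names sonication. Protocols, read numbers and the data of control samples were not analysed here.

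The deposited files were 8 lists of regions in narrowPeak format, 4 on ce11 and 4 on ce10. Per the deposited notes, each replicate's list and the list from pooled reads were called against a control alignment and served as input to the irreproducible discovery rate procedure (IDR), and the optimal list was derived from them. The peak caller, aligner, versions and IDR threshold are not given in the sources used here. Each input list held exactly 30000 regions, so the lists appear to be limited in length, and per the deposited notes they hold background as well as peaks. The authors gave each region a signal value (column 7), a −log10 q-value (column 9) and a summit offset. The deposited −log10 q-value reached a ceiling in each list (3.54 in the pooled ce11 list, shared by 1749 regions), so regions were ranked by the authors' signal and not by q. Region widths were nearly constant, at 330 bp in replicate 1 and 324 bp in replicate 2 and the pooled list. Signal values in the pooled list ran from 5.43 to 356.0, in replicate 1 from 2.79 to 128.5 and in replicate 2 from 3.00 to 269.2. They were not compared in size between lists, whose scaling is not stated.

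The ce11 lists were used with the WBcel235 genome, the same assembly, and the Ensembl 115 annotation (19973 protein-coding genes). The ce10 lists entered only as an alternative without annotation, and no coordinate was converted. Coordinates are given from 1. A summit was the region start plus the deposited offset. Summits matched at 100 bp or less. The promoter window ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start, and a summit outside it was placed in a coding exon, UTR, other exon, intron or intergenic sequence in that order. The background for each test was the 28083 pooled candidates with a summit over 100 bp from any optimal summit, which passed the same calling on the same reads. Whether it contains weak true sites was not tested, and such sites would narrow differences. Because the optimal list proved to be the strongest part of the pooled list, the tests compare strong with weak regions of that list.

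Before the data were examined, the tests, the alternatives, 22 gene lists and the rule for named genes were fixed. The rule named *lin-11* and *unc-119* in any case, the genes at the 15 strongest optimal peaks, the 4 bound genes of highest signal from each list past the test, every bound member of the LIM homeodomain, vulva and uterus, and *lin-11* neuron lists, the bound gene of highest signal from each other list, and the 10 most enriched and 3 most depleted 6-mers by p. List names were matched to annotated gene names, and 5 names had no match. A name shared by several genes stood for all of them, and histone genes and chemoreceptors include near-identical copies whose reads may be shared. Lists with fewer than 5 genes in the background were not tested. The background of list tests was the 8186 protein-coding genes with any candidate in the promoter window. A summit in the windows of several genes counted for each.

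Shares were compared by two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over lists, 6-mers, chromosomes or places. Odds ratio intervals are Woolf 95% intervals with 0.5 added to each cell, and share intervals are Wilson 95% intervals. Chance overlap came from 100 circular shifts per chromosome, and the interval of the rank correlation from 1000 bootstrap resamples of peaks. For sequence, 50 bp on each side of the summit were searched on both strands, and 6-mers were joined with their reverse complements. GC matching drew other candidates in 10 bins of GC content, which left a mean of 50.2% against 50.6% at optimal summits. Random positions numbered 30000. Alternatives covered summit distance, interval overlap, promoter window, gene assignment, background, sequence window, ce10, the stronger 50% of optimal peaks and each replicate left out. Where a replicate was left out of a test of position or sequence, the 1917 highest-signal regions of the other replicate stood in for the optimal peaks. An alternative added after seeing the data kept only the 1101 optimal peaks found among the strongest regions of both replicates.

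The list and 6-mer tests were tested on simulated data. For the gene lists, 8186 genes and a planted odds ratio of 5 were used. The ribosomal protein list (77 genes) was called enriched in 100% of 200 rounds and the cilia list (37 genes) in 97.5%. With no effect, any list was called enriched in 2.5% of rounds. Genes were drawn independently, whereas in the data a summit in several windows counted for each gene. For 6-mers, 2 words planted in 5% of simulated summits were called enriched and 0 of the other 2078 were. The simulated summits and background were random sequence of the same base composition, unlike those of the data. The 6-mer simulation therefore does not show how many words differences in composition or place would call. Calls of depletion were not counted for lists or 6-mers, so neither simulation covers the depleted ones. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.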

Results

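LIN-11 is a LIM homeodomain transcription factor of *Caenorhabditis elegans* that acts in vulval, uterine and neuronal cell fates. Its binding was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole L2 larvae, the second larval stage, of a strain that carries LIN-11 fused at its C terminus to GFP and FLAG. The data form 1 group of 2 biological replicates, with no second condition, so the comparisons are between the replicates and between the authors' optimal peaks and the remaining candidate regions. Each replicate contributed a list of 30000 candidate regions on the ce11 assembly, and a list of the same length came from the pooled reads. The authors' optimal list, described as a product of the irreproducible discovery rate procedure, held 1917 peaks that covered 0.605% of the genome, against 9.51% for the pooled candidates. Read depths are not given in the sources used here, so the depth behind each signal value is unknown, and intervals on shares cover the counting of regions only.

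The first question was how well the replicates recovered the same sites. Of the 1917 optimal peaks, 1752 had a candidate summit within 100 bp in both replicates, which is 91.4% (95% Wilson interval 90.1 to 92.6%). After circular shifts of the summits along their chromosomes the mean share was 1.41%, and the highest of 100 shifts gave 2.35%. The optimal peaks come from the pooled reads of these same replicates, so a match in each replicate's list is partly built in, and the shifts do not allow for that. The strongest peak, upstream of the ribosomal protein gene *rpl-3*, ranked 6 in replicate 1 and 1 in replicate 2. The peak shared by *tasp-1*, which encodes a taspase homologue, and K01G5.10 ranked 1 and 2, and the *rpl-35* peak ranked 3 in both lists. A comparison of the replicates' own lists, limited to their strongest regions, gave a lower share: 1092 of the 1917 highest-signal regions of replicate 1 (56.96%, 54.7 to 59.2%) lay within 100 bp of one of the 1917 highest-signal regions of replicate 2, against a mean of 0.400% after shifting. With 5 times as many regions from each list the share was 30.3%.

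Signal values are the authors' own per-region values, and they were used only to rank or describe regions within a list. Over the 1752 matched peaks, replicate 1 and replicate 2 signals had a Spearman rho of 0.426 (95% bootstrap interval 0.388 to 0.467). This is a correlation across peaks, which are not independent replicates, so no p-value was computed. The rho was 0.309 in the stronger 50% of the optimal peaks and 0.568 over all 7506 pooled candidates matched in both replicates. Optimal peaks were those of highest pooled signal, so 0.426 describes agreement within that selected range only. Of the optimal peaks, 1101 (57.4%, 55.2 to 59.6%) had a match among the 1917 strongest regions of both replicates, 507 (26.4%) in replicate 2 only, 244 (12.7%) in replicate 1 only and 65 (3.39%) in neither. The optimal list was identical to the 1917 pooled regions of highest signal. An optimal peak was not necessarily strong in each replicate. The *glr-6* and *daf-19* peaks, for example, had no replicate 1 candidate within 100 bp.

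**Figure D1:**
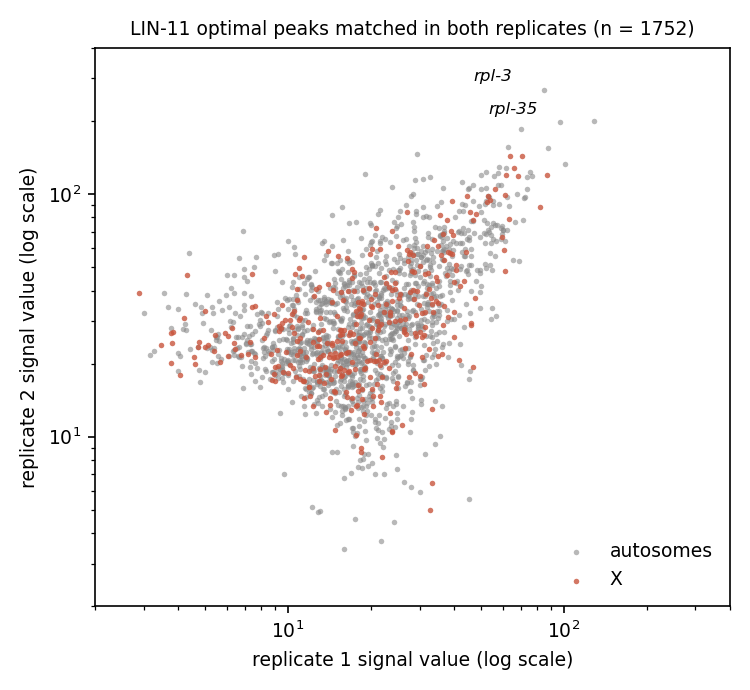
Signal value in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale) at the 1752 optimal peaks matched within 100 bp in both replicates. Points are peaks, coloured by X or autosomes; the Spearman rho was 0.426, and *rpl-3* and *rpl-35* lie at the upper end in both replicates.

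LIN-11 peaks were concentrated at promoters and nearly absent from coding sequence. The summits of 1243 of 1917 optimal peaks (64.8%, 62.7 to 66.9%) lay from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, against 8320 of 28083 other pooled candidates (29.6%). The odds ratio was 4.38 (95% interval 3.97 to 4.83; two-sided Fisher exact p = 2.34e-206). Coding exons outside these windows held 18 optimal summits (0.939%) and 29.1% of the other candidates, with an odds ratio of 0.0230 (Fisher exact, adjusted p = 6.68e-240 over 6 kinds of place). Introns held 245 optimal summits (12.8%) against 21.8% of other candidates, an odds ratio of 0.525 (Fisher exact, adjusted p = 1.54e-22). Intergenic sequence held 400 (20.9%) against 17.6%, an odds ratio of 1.24 (Fisher exact, adjusted p = 4.09e-04). Neighbouring peaks are not independent, so these p-values are too small. The other candidates were themselves placed unevenly, since 19.1% of random genome positions fell in coding exons.

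**Figure D2:**
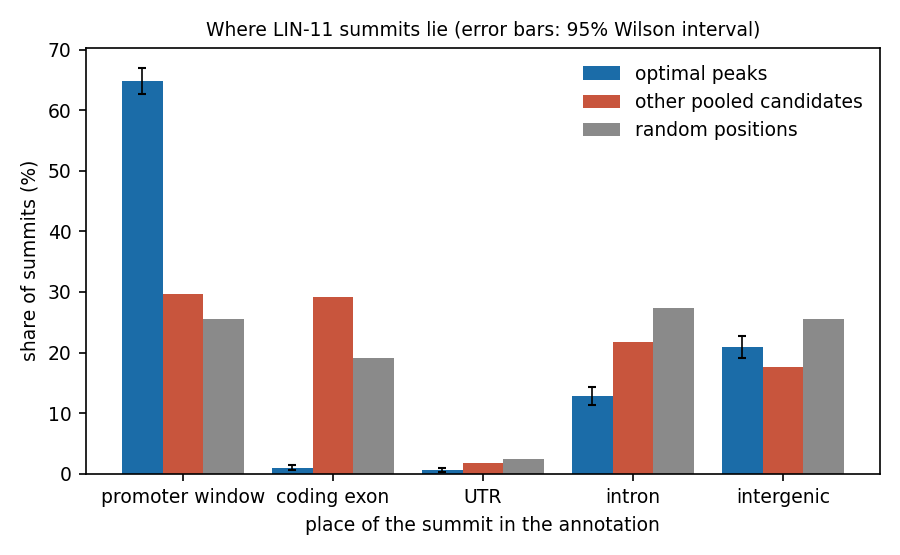
Share of summits (y axis, %) in each kind of annotated place (x axis) for optimal peaks, other pooled candidates and random genome positions, with 95% Wilson intervals on the optimal peaks. Promoter windows take precedence over the other places, and exons that are neither coding nor UTR (0 optimal summits) are left out; promoters hold 64.8% of optimal summits against 29.6% of other candidates, and coding exons 0.939% against 29.1%.

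The 15 strongest peaks included promoters of ribosomal protein, chaperone, translation factor and secretion genes. The first lay at III:3867467-3867677, with its summit 282 bp upstream of *rpl-3* (WBGene00004414), and had a pooled signal of 356.0. The second lay at III:10759131-10759370 in the promoter windows of *tasp-1* and K01G5.10, with a signal of 329.6. The third, at III:7854595-7854789, was 449 bp upstream of *rpl-35* and had a signal of 286.0. The fourth, at III:1619050-1619239 with a signal of 254.4, lay in the promoter windows of *hsp-60*, the mitochondrial chaperonin gene, and Y22D7AL.10. The fifth (signal 237.3) lay in those of *iff-2*, which encodes the translation factor eIF5A, and F54C9.14. The sixth (232.0) was at *egl-30*, the Gq alpha subunit gene, and C53H9.4, and the seventh (220.8) at *rpl-15* and K11H12.8. Lower in the same group were promoters of *sec-61.G* with F32D8.13 (195.0), which encodes a translocon subunit, *nhl-2* with *tag-340* (194.3), the Pumilio-family gene *puf-9* (193.8) and *egg-5* (190.4).

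Of these 15 peaks, 4 lay in no promoter window, and 3 of those were on X. The first X peak, at X:4209196-4209356, was intergenic and 1795 bp upstream of F20B6.9, with a signal of 209.8. The second, at X:11094154-11094309, was intergenic with W02H3.3 as the gene of the nearest start, 3942 bp away, and had a signal of 209.8. The third, at X:6296480-6296636, was in an intron of a protein-coding gene, 3399 bp upstream of *cest-16*, and had a signal of 206.8. The remaining peak lay on chromosome I, 1892 bp upstream of the casein kinase gene *csnk-1*, and is described with *lin-11*.

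Chromosome X carried more of the optimal peaks than of the other candidates. It held 404 of 1917 optimal peaks (21.1%, 19.3 to 22.96%) and 5001 of 28083 other candidates (17.8%), with an odds ratio of 1.23 (1.10 to 1.38; two-sided Fisher exact p = 4.09e-04), and it makes up 17.7% of the nuclear genome. Chromosome V held 257 optimal peaks (13.4%) against 17.9% of other candidates, an odds ratio of 0.712 (Fisher exact, adjusted p = 2.12e-06 over 6 chromosomes). Chromosome III held 353 (18.4%) against 16.2%, an odds ratio of 1.17 (adjusted Fisher exact p = 0.0232), and chromosome II 282 (14.7%) against 16.8%, an odds ratio of 0.854 (adjusted Fisher exact p = 0.0262). Chromosomes I and IV did not pass the test (adjusted Fisher exact p = 0.0850 and 0.527). On X, 56.2% of optimal peaks were at promoters against 67.2% on the autosomes, an odds ratio of 0.627 (Fisher exact p = 5.10e-05). The other candidates differed in the same direction, with 26.3% at promoters on X and 30.3% on the autosomes. In the stronger 50% of optimal peaks the X odds ratio was 1.13 and did not pass the test (Fisher exact p = 0.133). For optimal peaks in the top list of both replicates it was 1.19 (Fisher exact p = 0.0275). Peaks along a chromosome are not independent, so the p-values for chromosomes are also too small.

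The *lin-11* gene itself (WBGene00003000, I:10248288-10255327, plus strand) carried 5 optimal peaks within it or at its promoter. The strongest, at I:10250079-10250232 in an intron with its summit 1868 bp past the gene's start, had a pooled signal of 152.7 and rank 39. Its signal was 53.5 in replicate 1 and 96.9 in replicate 2. A second intronic peak, at I:10252649-10252972 and 4523 bp past the start, had a pooled signal of 107.4, with 44.4 in replicate 1 and 65.0 in replicate 2. The other 3 were weaker, with pooled signals of 30.8 at the promoter (summit 27 bp upstream of the start), 32.0 in an intron 403 bp past the start and 32.0 in an intron 5965 bp past it. In the same order their signals were 8.93, 7.15 and 8.18 in replicate 1 (ranks 4124, 6705 and 4973) and 27.6, 22.4 and 22.3 in replicate 2 (ranks 1002, 1351 and 1366), so these 3 were not among the 1917 strongest regions of replicate 1. Upstream, an intergenic peak at I:10235116-10235439 had a signal of 198.9 and rank 11, with its summit 13010 bp before the *lin-11* start. At *unc-119*, whose mutant allele forms part of the strain's genotype, there was 1 optimal peak, in an intron at III:10903342-10903665, with a pooled signal of 33.1 and rank 1530. Its signal was 4.26 in replicate 1 (rank 17713) and 27.4 in replicate 2 (rank 1010), so it was not among the 1917 strongest regions of replicate 1. Because the strain carries a *lin-11* transgene, reads from the native and the introduced copies cannot be separated here. The same would hold at *unc-119* if the transgene carries that gene, which was not examined.

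**Figure D3:**
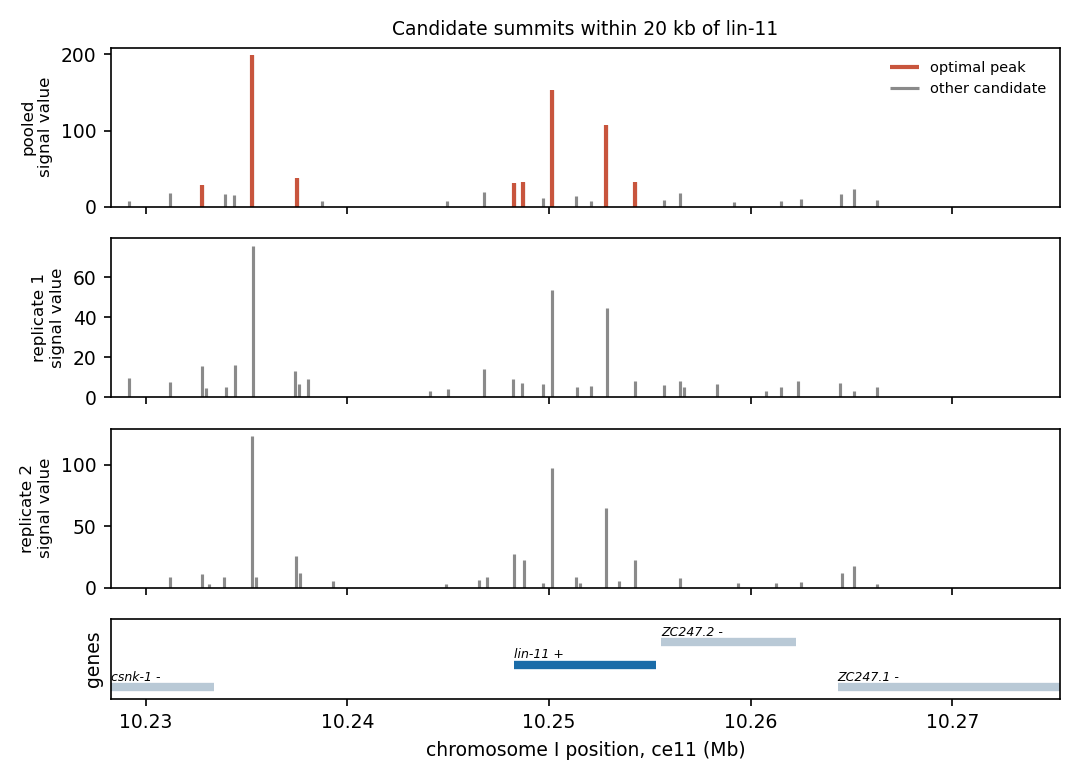
Candidate summits within 20 kb of *lin-11* on chromosome I (x axis, ce11 position in Mb), with the signal value of each as the height of its line (y axis, each panel on its own scale) in the pooled list and in each replicate; the lowest panel shows protein-coding genes with their strand. Red lines are optimal peaks, the tallest at 198.9 upstream of *lin-11* and at 152.7 and 107.4 within it, and the same 3 positions are the tallest in both replicates.

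Ribosomal protein genes stood apart among the genes bound at their promoters. In all, 1675 protein-coding genes had an optimal peak in the promoter window, out of 8186 with any candidate there. Of 77 ribosomal protein genes with a candidate, 65 (84.4%) were bound, against 19.9% of other genes, an odds ratio of 21.9 (11.5 to 38.8; two-sided Fisher exact, adjusted p = 3.39e-32 over the 21 lists tested). The highest signals were at *rpl-3*, *rpl-35*, *rpl-15* (220.8) and *rps-19* (185.8), and 17 of the 65 bound genes had a peak among the 100 strongest. The odds ratio was 26.9 without replicate 1 and 20.5 without replicate 2, and it ran from 9.35 with the nearest transcript start only to 52.7 with all protein-coding genes as background. No other fixed list was enriched in the planned test. Heat shock genes (6 of 13 bound, led by *hsp-60*, signal 254.4) had an odds ratio of 3.34 and histone genes (7 of 17, led by *his-37*, 150.2) one of 2.73, and neither passed (adjusted Fisher exact p = 0.116 and 0.145). Heat shock genes passed with all protein-coding genes as background and in the stronger 50% of peaks (adjusted Fisher exact p = 0.0367 and 0.0115), and histone genes passed without replicate 1 (adjusted Fisher exact p = 0.0352).

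Of the sensory and signalling lists, 3 were bound less often than other genes, as were cuticle genes. GC content, which differed between optimal summits and other candidates, was not matched for these lists, so its part is unknown. Chemoreceptors had 7 of 260 genes bound, an odds ratio of 0.104 (Fisher exact, adjusted p = 1.20e-16), with the highest signals at *srh-16* (74.3), *sri-5* (74.2), *sre-23* (57.9) and *srr-10* (44.6). Neuropeptides had 1 of 60, the insulin-like gene *ins-39* with a signal of 106.8 (odds ratio 0.0653, adjusted Fisher exact p = 2.24e-04). Ion channels and receptors had 2 of 61, the glutamate receptor gene *glr-6* (31.3) and the potassium channel gene *twk-14* (31.1), with an odds ratio of 0.131 (adjusted Fisher exact p = 9.54e-04). Collagen and cuticle genes had 2 of 51, *col-38* (121.7) and *col-71* (30.6), an odds ratio of 0.158 (adjusted Fisher exact p = 0.00588). Several of these values rested on few genes and moved when a replicate was left out. Without replicate 1 the odds ratio was 0.193 for chemoreceptors, 0.149 for neuropeptides and 0.0540 for ion channels and receptors, and all 3 lists passed. Without replicate 2 it was 0.324 for neuropeptides and 0.386 for cuticle genes, and these lists no longer passed (adjusted Fisher exact p = 0.101 and 0.220). The cuticle list also missed the threshold with the shorter promoter window, the nearest transcript start only and the stronger 50% of peaks (adjusted Fisher exact p = 0.0657, 0.233 and 0.0926). With the longer promoter window the odds ratio was 0.208 for neuropeptides and 0.379 for ion channels and receptors. In the same order it was 0.257 and 0.327 with the nearest transcript start only, and 0 and 0.134 with the shorter window. Both lists passed in each of these settings.

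Lists tied to the known roles of *lin-11* showed no detectable difference from other genes in optimal peaks at their promoters. Bound here means an optimal peak in the promoter window, and 674 optimal peaks lay in no such window. More distant or intronic peaks of these genes were therefore not counted. In the vulva and uterus list 3 of 16 genes with a candidate were bound, an odds ratio of 0.897 (0.311 to 3.27; Fisher exact p = 1, adjusted p = 1), and 22 of its 25 annotated genes were not. The bound members were *lin-7*, which encodes a PDZ protein of the LET-23 receptor complex (signal 122.1), the fibroblast growth factor gene *egl-17* (44.1) and the zinc-finger gene *egl-43* (29.9). Among identity genes of neurons that express *lin-11* or lie in its circuits, 1 of 6 was bound, the dense-core vesicle gene *ida-1* (29.4), and 13 of 14 annotated genes were not (odds ratio 0.777, Fisher exact p = 1, adjusted p = 1). The direction for this list turned with the replicate left out, from 2 of 6 bound (odds ratio 1.99) without replicate 1 to 0 of 10 without replicate 2, and the vulva and uterus list had odds ratios of 1.09 and 0.542; neither list passed in either case. Of the 8 LIM homeodomain genes and cofactor, *lin-11* was bound (promoter peak 30.8) and 7 were not; without replicate 2 none was bound, with 0 of 4 in the background. That list had 2 genes in the background and was not tested in the planned setting. With each peak given to the nearest transcript start only, 2 of 7 of its genes were bound (odds ratio 2.48). In that setting the neuron list had 2 of 12 bound (1.24) and the vulva and uterus list 3 of 20 (1.09). None of these passed the test. The intervals are wide, so a moderate difference in either direction was not detectable with so few genes. Only whole larvae of the L2 stage were sampled, so binding at other stages was not seen, and binding in few cells could be missed.

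None of the remaining 12 lists passed the planned test. Transcription factor lists had 4 of 41 homeobox genes bound, led by *ceh-38* (83.2), 3 of 18 bHLH genes, led by *mdl-1* (76.5), and 12 of 95 nuclear hormone receptor genes, led by *nhr-47* (131.3), with adjusted Fisher exact p-values of 0.248, 1 and 0.145. Without replicate 1 the nuclear hormone receptors were bound less often than other genes (odds ratio 0.430, adjusted Fisher exact p = 0.0205), as they were with the shorter and the longer promoter window and with all protein-coding genes as background (adjusted Fisher exact p = 0.0492, 0.00806 and 0.0474). Neuronal lists had 5 of 25 synaptic and transmitter genes, led by the vesicle GTPase gene *rab-3* (91.0), 1 of 25 axon guidance genes, the netrin receptor gene *unc-40* (67.2), and 5 of 37 cilia genes, led by the RFX factor gene *daf-19* (54.5), with adjusted Fisher exact p-values of 1, 0.133 and 0.578. Axon guidance genes, with an odds ratio of 0.161, had 2 of 29 bound (0.294) without replicate 1 and 4 of 26 (0.739) without replicate 2, and cilia genes had 7 of 33 bound (odds ratio 1.07, against 0.606) without replicate 1. With each peak given to the nearest transcript start only, 15 of 38 synaptic and transmitter genes were bound (odds ratio 4.07, adjusted Fisher exact p = 6.31e-04). The Wnt list had 2 of 15 bound, led by the Dishevelled gene *mig-5* (150.4), with an adjusted Fisher exact p of 0.943. Marker lists of other tissues had 2 of 24 body wall muscle genes bound, led by *act-4* (50.6), 4 of 17 germline genes, led by the helicase gene *cgh-1* (70.6), 2 of 21 hypodermal genes, led by the heterochronic gene *lin-28* (47.2), 0 of 9 intestinal genes and 0 of 10 pharyngeal genes. Their adjusted Fisher exact p-values were 0.372, 0.943, 0.427, 0.372 and 0.372. Of the other lists here, bHLH genes went from an odds ratio of 0.777 to 1.45 without replicate 1, body wall muscle genes from 0.353 to 0.189 without replicate 1 and 0.554 without replicate 2, germline genes from 1.20 to 0.997 and 0.814 in the same order, and without replicate 2 Wnt genes went from 0.598 to 0.313 and hypodermal genes from 0.408 to 1.63. None of these passed the test with a replicate left out.

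**Figure D4:**
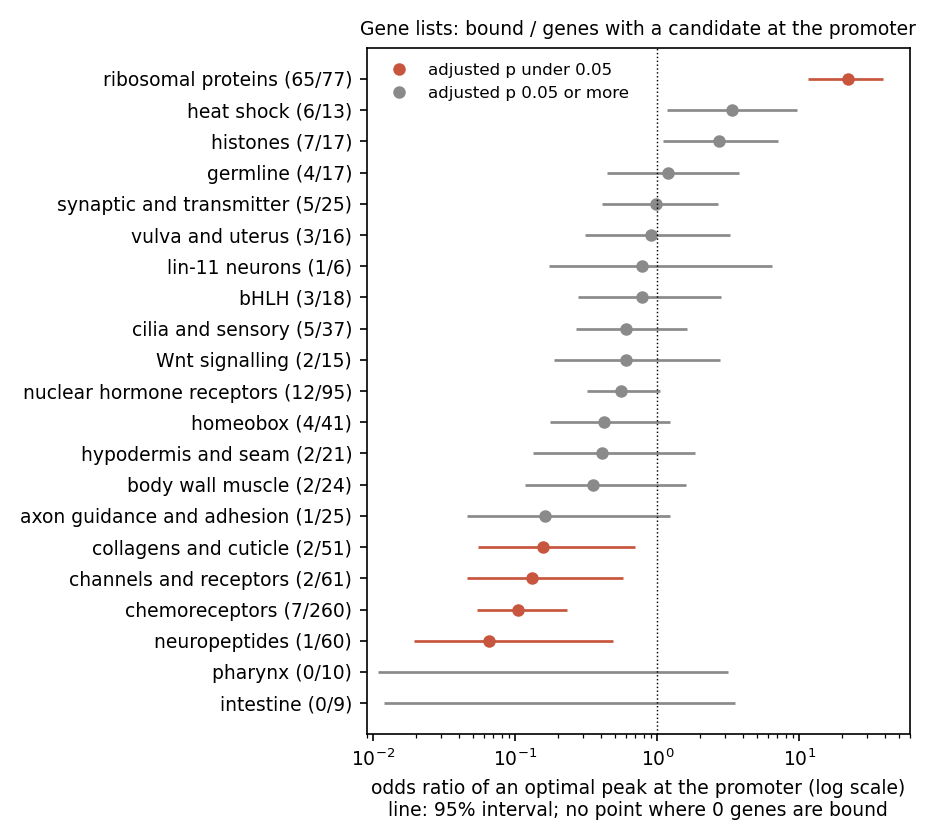
Odds ratio (x axis, log scale) that a gene of each list has an optimal peak at its promoter, against other genes with a candidate there, for the 21 lists tested (y axis, with bound genes over genes with a candidate). Lines are 95% intervals, and colour marks an adjusted Fisher exact p under 0.05; ribosomal proteins lie at 21.9, and chemoreceptors, neuropeptides, channels and receptors, and collagens lie below 1.

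The last comparison asked which short sequences mark the summits. TAATTA, a core site of many homeodomains, occurred within 50 bp of 20 of 1917 optimal summits (1.04%, 0.676 to 1.61%) and of 696 of 28083 other candidate summits (2.48%), an odds ratio of 0.415 (0.273 to 0.661; two-sided Fisher exact p = 1.79e-05). The odds ratio was 0.638 without replicate 2 and 0.793 with 100 bp searched on each side. Optimal summits were richer in G and C, with a mean of 50.6% (SD 6.04 over 1917 summits) against 43.2% (SD 8.23 over 28083 summits). Against other candidates matched on GC content the odds ratio was 0.932 and did not pass the test (Fisher exact p = 0.903), so no difference in TAATTA was detectable beyond base composition.

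Of the 6-mers tested, 600 were enriched at optimal summits and 713 were depleted (Fisher exact, adjusted p under 0.05). Against GC-matched candidates 586 were depleted and 420 enriched, and 347 of the enriched were among the 600. Of the 10 enriched words with the smallest p, ACGCAG was found at 19.6% of optimal and 3.92% of other summits (odds ratio 5.97, adjusted Fisher exact p = 3.12e-126), GACGCA at 18.99% and 4.07%, and AGACGC at 17.4% and 3.96%. GCGCGC was found at 11.9% and 1.61% (odds ratio 8.27), ACGCGC at 15.02% and 2.72%, and GCGCAC at 14.3% and 2.71%. AGAGAG was found at 24.4% and 6.59% (odds ratio 4.58), GAGAGA at 27.2% and 8.17%, AGAGAC at 19.9% and 5.33%, and CGTCTC, counted with its complement GAGACG, at 21.02% and 5.59%. The 3 depleted words with the smallest p were AAAATT at 11.4% and 28.1% (odds ratio 0.328), CTGAAA at 5.27% and 16.3% (0.287), and AAATTT at 5.74% and 16.7% (0.304). With GC-matched candidates GAGAGA kept an odds ratio of 3.17 (adjusted Fisher exact p = 3.03e-66) and ACGCAG one of 4.33 (adjusted Fisher exact p = 1.42e-72). All 3 depleted words still passed there, with odds ratios of 0.825 for AAAATT, 0.756 for AAATTT and 0.490 for CTGAAA (adjusted Fisher exact p = 0.0332, 0.0201 and 3.31e-11). AGACGC, GACGCA and ACGCAG overlap, so they may count the same sites. Neither the 6-mer tests nor those of TAATTA matched the place of the summits. Coding exons held 0.939% of optimal summits and 29.1% of other candidates, and promoter windows 64.8% and 29.6%. The words may therefore partly separate promoter from coding sequence, which was not tested. Overlap is also not limited to the 3 enriched words named for it above. Each of the 10 enriched words, or its complement, overlaps another of the 10 when shifted by a few bases. The words of alternating A and G join those 3 words through such overlaps. The 10 words therefore need not be separate signals, and how often they share a summit was not tested.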

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

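The alternative that keeps only optimal peaks found among the strongest regions of both replicates was chosen after seeing the data; the others were planned. The share of optimal peaks supported in both replicates moved with the matching rule: 74.1% at 50 bp, 97.8% at 200 bp, 93.7% with reciprocal 50% interval overlap and 94.7% in the stronger 50% of peaks. Support in a single replicate, with the other left out, ran from 93.1 to 98.02%. The overlap of the strongest regions was 46.1% at 50 bp, 62.5% at 200 bp, 59.6% with the list halved in length and 30.3% with 5 times as many regions, where the lists reach into weak candidates. A longer matching distance raises both shares by construction, and asking for 1 replicate in place of both raises the share supported; the cause of the other shifts was not tested. The signal correlation was 0.309 in the stronger 50% of peaks, a narrower range of signal, and 0.568 over all 7506 pooled candidates matched in both replicates.

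The promoter odds ratio passed under all 7 alternatives (3.85 to 6.15, the highest in the stronger 50% of peaks). The X odds ratio passed under 5 of 6 and was 1.13 (Fisher exact p = 0.133) in the stronger 50%, which has fewer peaks; the cause was not tested further. The TAATTA odds ratio stayed below 1 under all 6 and lost the test with GC-matched candidates (0.932, Fisher exact p = 0.903), where base composition no longer differs much. The count of enriched gene lists was 1 and became 2 with the nearest transcript start only, where synaptic and transmitter genes were added (15 of 38, odds ratio 4.07), 2 with all protein-coding genes as background and 2 in the stronger 50% of peaks, where heat shock genes were added in each case. With 1 replicate left out it ran from 1 to 2; histone genes were added without replicate 1 (7 of 14, odds ratio 3.999). The cause of these additions was not tested. Ribosomal proteins remained enriched under all 8. The number of enriched 6-mers ran from 420 to 613 over the 6 alternatives, and the number of optimal peaks was 1835 on ce10 and 1897 after merging overlaps. With read depth unknown, no limit from depth can be given.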

Other observations

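The descriptions in the next 2 paragraphs, and the test of the *lin-11* region below, were chosen only after the results were seen. Leaving out each replicate was planned, but its use below to weigh an explanation was also chosen after. The tests on base composition, repeats and GCGCAGGG were written before their results. Optimal summits lay near tRNA, snoRNA and snRNA genes more often than other candidates. Within 200 bp of a tRNA gene were 123 optimal summits (6.42%) against 0.947% of other candidates, an odds ratio of 7.17 (5.77 to 8.94; Fisher exact, adjusted p = 1.67e-51 over 7 kinds of gene). For snoRNA genes there were 69 (3.599%) against 0.360%, an odds ratio of 10.3 (7.61 to 14.1; adjusted Fisher exact p = 3.28e-37), and for snRNA genes 12 (0.626%) against 0.0997%, an odds ratio of 6.31 (adjusted Fisher exact p = 8.15e-06). The lincRNA genes had an odds ratio of 2.45 (adjusted Fisher exact p = 0.0152). For miRNA and piRNA genes the test was not passed (adjusted Fisher exact p = 0.169 and 0.908), and pseudogenes were near fewer optimal summits, with an odds ratio of 0.233 (adjusted Fisher exact p = 2.82e-08). Many tRNA and snRNA genes have near-identical copies, and 3.29% of optimal summits lay in mostly repeated sequence against 1.69% of other candidates.

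Shared promoters were common. Of the 1243 optimal peaks at promoters, 441 (35.5%, 32.9 to 38.2%) lay in the windows of at least 2 genes, against 11.9% of the 8320 other candidates at promoters (odds ratio 4.06, Fisher exact p = 3.63e-85). Sequence changed along the pooled ranking. TAATTA was within 50 bp of 1.00% of the 500 strongest summits and of 2.92% of those ranked 20001 to 30000, while GAGAGA fell from 27% to 6.25% and mean GC content from 52.3% to 41.3%. Promoter windows held 74.2% of the 500 strongest summits and 26.6% of the weakest 10000.

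Ribosomal protein promoters, 65 of 77 bound, are the clearest gene group, and base composition was weighed first because their strongest candidate summits averaged 50.3% GC against 44.4% at other genes. In 10000 draws of other genes matched on GC content a mean of 23.7 genes were bound and the highest draw reached 39, which argues against composition as the whole cause. The signal of a single replicate is also argued against: the lower 95% bounds of the odds ratio in the replicates taken alone were 11.04 or more. What stays open is whether the tagged protein occupies these promoters by its own sequence preference, or whether active or open promoters are recovered whatever the factor, which may go with the tRNA and snoRNA neighbours. Telling these apart needs other factors, an untagged control or expression values, not analysed here, and no biological explanation was tested.

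The *lin-11* region held 8 optimal peaks within 20 kb of the gene, in a window of 47040 bp. Windows of that width around 1909 other optimal peaks held a median of 2 and at most 7. A candidate explanation is that extra copies of the region, carried by the transgene, raise all of its DNA. The number of candidates there that were not optimal peaks was 18, against a median of 15 and a 95th percentile of 26 in the other windows, but this count decides nothing, because extra copies could also raise candidates into the optimal list. The explanation cannot be told apart from binding of LIN-11 at its own gene. It stays open because the number and extent of the introduced copies are unknown here, as is the strain of the control alignment: a control from the tagged strain would already correct for extra copies.

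The excess of optimal peaks on X was larger outside promoters (26.3% against 18.7%, odds ratio 1.55, Fisher exact p = 1.85e-06) than at promoters (18.3% against 15.8%, odds ratio 1.19, Fisher exact p = 0.0315); the difference between these was not tested. Against GC-matched candidates the X odds ratio was 1.20 (Fisher exact p = 0.00394). Without mostly repeated summits it was also 1.20 (Fisher exact p = 0.00246). In these tests neither composition nor repeats alone accounted for the whole excess. The p-values treat neighbouring peaks as independent and are too small. Coding exons, which held 0.939% of optimal summits and 29.1% of other candidates, were not matched between X and autosomes. The part of place in the excess is therefore unknown. GCGCAGGG, a core sequence known from the X sites that recruit the dosage compensation complex, lay within 100 bp of 15 of 404 optimal summits on X and 0 of 1513 on autosomes (Fisher exact p = 5.83e-11), but at 0.180% and 0.160% of other candidates on X and autosomes (Fisher exact p = 0.702). The 3 strongest X peaks, all outside promoters, had it. Removing every summit with this exact sequence left an X odds ratio of 1.19 (Fisher exact p = 0.00410). Exact matches, at 15 of 404 optimal summits on X, are therefore too few to be the whole cause. Recruitment sites without an exact match were not removed, so their share in the excess stays open. The hypothesis that LIN-11 ChIP recovers dosage compensation recruitment sites may merit a comparison with maps of that complex.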
